A study of Mus musculus with 9 samples.

How the data were processed

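Total RNA of neck skin from male C57BL/6 mice was hybridised to 9 Affymetrix mouse arrays, 3 of control skin and 3 each of skin challenged with oxazolone or urushiol. Groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression values, 1 per transcript cluster and array. Affymetrix Expression Console 1.4, the RMA method and the Transcriptome Analysis Console are named in the submitters' processing notes, with no role or order. RMA by its definition corrects the background, normalises between arrays by quantiles and summarises probes per cluster. The log2 values run from 2.20 to 19.93, and the step that carries them past 16, the log2 limit of a 16-bit scanner, is not given in the sources used here, so log2 differences may not equal log2 ratios of RNA amounts. Values at the ceiling of 19.93 were present for 7 genes on control array 1, 0 on control array 2 and 3 on each other array, and the size of differences that involve them is not known. The genome build is not given in the sources used here, and no coordinates were used.

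Of 72688 features, 6732 were array controls and were left out. The platform annotation gave 1 gene symbol to 30604 of the 65956 transcript clusters, several to 2146 and none to 33206, and genes were named only from clusters with 1 symbol. Symbols of 827 clusters (819 genes) were updated through the gene ID to a RefSeq gene table for the mouse assembly GRCm38, used for names alone. Each gene was represented by its cluster with the highest mean over all 9 arrays, which gave 30142 genes. In 355 genes with more than 1 cluster, clusters were called in opposite directions for Fas and Itgb1bp1 in urushiol against control and for no gene in the other comparisons. The file holds no detection calls, so dimness was judged only against the median of all clusters of an array, which lay between 5.53 and 5.64. Genes below it on most arrays were kept, and the arrays carry no depth: their number limits the precision, with a median standard error of 0.113 log2 units per comparison.

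Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in 1 fit of all 9 arrays, with Benjamini-Hochberg adjustment over 30142 genes and a threshold of 0.05. A moderated F test covered any difference among the 3 groups. There were 27 gene lists with 543 symbols, of which 488 were measured, and counts of members were given over all genes and adjusted over the list alone. The competitive limma test camera was run with its preset correlation of 0.01 and an estimated one, and fry as the self-contained test of whether members move one way on balance. Benjamini-Hochberg adjustment covered 26 lists per comparison. With the preset correlation camera called 19, 15 and 12 lists in the order oxazolone, urushiol and allergens compared, and with an estimated correlation 0 in each, so no list call holds under both. The erythrocyte list, with 2 measured members, was left out of the list tests. Adjusted p values of genes are limma's, and those of lists camera's unless fry is named.

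Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The alternatives added later were a hair follicle score as a covariate, after control array 3 was seen to lie apart, and the fit of 6 arrays with the replicate number as a block, after the check of the pairing. The rule named, per comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap, without predicted genes or receptor segments, 2 to 4 members of each list by size of change, and 23 genes chosen beforehand. Not all of the 23 had a cluster with 1 symbol, and Krt6b was without one. Other named genes were chosen after their values were seen, as members of short counts or as members that moved against their list: Cd5, Cdk1, Rrm2, Mcm3, Mcm4, Krt84, Cd3g, Cd4, Ifngr1, Il12rb2, Ccr4, Il31ra, Slc6a4, Penk, Flg2, Col1a1, Col1a2, Il15, Icam1, Ereg, Itga5, Defb4 and Dgat2, and the genes named only in the closing part, apart from those its tests listed beforehand.

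Whether replicate numbers pair the arrays was checked by correlating deviations from the group means. Same-numbered oxazolone and urushiol arrays correlated at 0.201, 0.197 and 0.124, all above 0.1, so numbers were taken to pair them, though no label does. Of all 9 same-numbered pairs (-0.232 to 0.337) 4 lay below 0.1, so controls were not paired. The 18 other pairs reached 0.285, with 13 below 0.1, so 0.1 is weak evidence. The main fit was unpaired, and a block by number an alternative throughout. The other alternatives were a filter on dim genes, the mean of a gene's clusters, all clusters for themselves, quantile renormalisation, median centring, trended, robust and unmoderated variances, array weights, 2 groups alone, other thresholds, treat at a log2 fold change of 0.5, and leaving out each array in turn. The alternative that prefers clusters without a cross-hybridisation marker was not run, because these identifiers carry none.

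The steps were tested on simulated data with the real spread of 30142 genes. At log2 changes of 0.5, 1 and 2, the fit recovered 46.3%, 71.6% and 93.9% of changed genes for oxazolone against control, with 14 unchanged genes called, and 48.5%, 70.6% and 97% for urushiol against control, with 6. For the direct comparison it recovered 17.6%, 69.7% and 78.8%, with 1 unchanged gene called. The first criterion set for this test asked for nearly all genes with a log2 change of 2. It was missed for the direct comparison, and it was replaced by one on the size of the estimates, whose mean was 1.97 there against a true 2. Both lists that were shifted in the simulation were called with the preset and with an estimated correlation, and no others with the preset one. Genes were drawn independently there, while real lists had estimated correlations of up to 0.949, so camera with correlated members stays untested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.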

Results

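Neck skin of male C57BL/6 mice, an inbred strain, was measured on 9 Affymetrix arrays, 3 in each of 3 groups. Control skin was described as healthy. The other groups had allergic contact dermatitis raised with oxazolone, a synthetic hapten, or with urushiol, the allergenic oil of poison ivy and its relatives. Both allergens were applied at 2.0% to the abdomen for sensitisation and, from 5 days later, at 0.5% in 40 µl acetone to the nape for 5 challenges, the last on day 8, and skin was taken 4 hours after it. Whether control mice were shaved or painted with acetone is not given in the sources used here, so neither can be separated from the allergens against control. The study was framed around immune responses and itch in these models, which sets 3 questions: what each allergen changed against control skin, and where the allergens differed. The labels call the replicates biological, and an exact permutation test of 3 arrays against 3 cannot go below p = 0.1. As the scale above log2 16 is unexplained, log2 changes below may not equal log2 ratios of RNA amounts. In the text, ± is the standard error of a log2 difference between groups of n = 3 arrays.

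Control array 3 stood apart from the other controls. It correlated at 0.978 to 0.979 across genes with control arrays 1 and 2, which correlated at 0.995 with each other, and genes are not independent replicates. On the first principal component, which held 74.0% of the variance, it lay at -46.8, against -118 and -122 for the other controls and 29.5 to 58.5 for the 6 challenged arrays. Relative to the control mean, its hair follicle list mean was 2.99 (log2), its cell division mean 1.26, its melanocyte mean 1.64 and its skeletal muscle mean -1.61. Control arrays 1 and 2 had hair follicle means of -1.53 and -1.45, cell division means of -0.45 and -0.81, melanocyte means of -0.81 and -0.83 and muscle means of 0.84 and 0.77. On all 9 arrays, the Y-linked genes Kdm5d, Eif2s3y and Uty lay between 8.74 and 11.21, and Xist between 4.93 and 5.24, in mice labelled male.

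**Figure D1:**
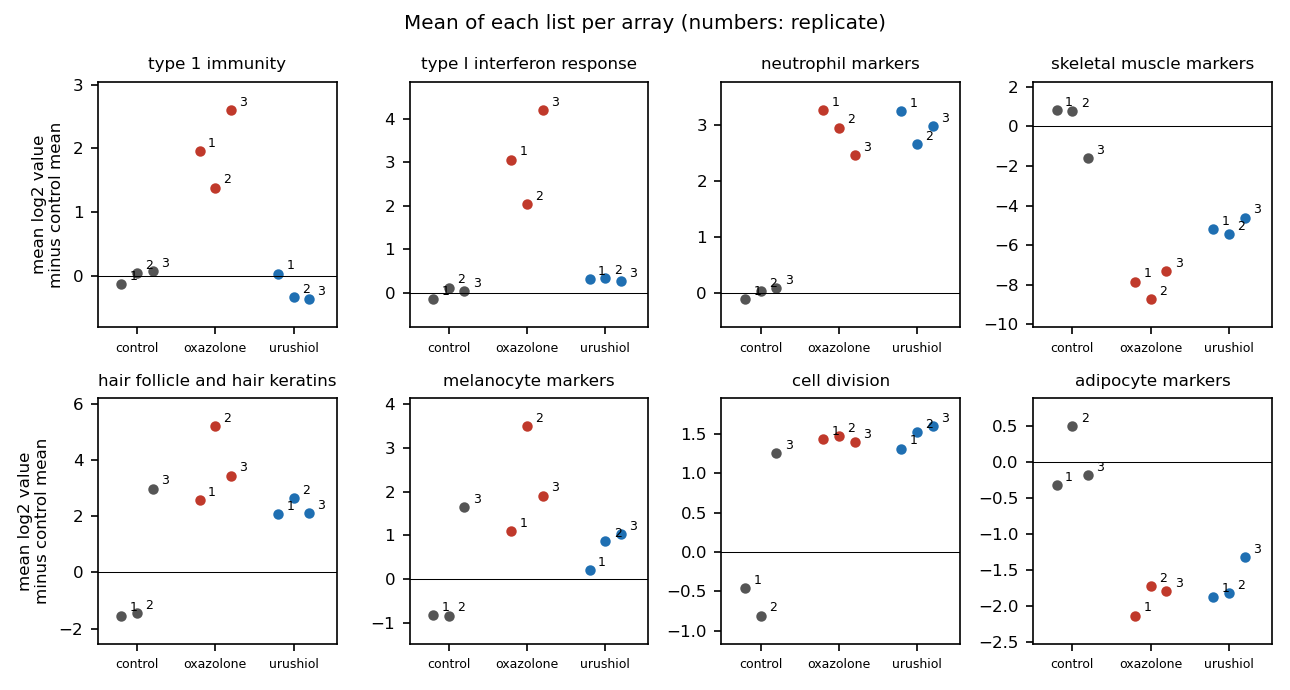
Mean of the measured members of 8 gene lists on each array, in log2 units relative to the mean of the 3 control arrays, with the replicate number beside each point. Control array 3 lies apart from control arrays 1 and 2 for hair follicle (2.99), cell division (1.26), melanocyte (1.64) and muscle genes (-1.61), and the oxazolone arrays lie above the urushiol arrays for both interferon lists.

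In oxazolone-challenged skin, chemokines induced by interferon gamma, epidermal stress genes and neutrophil genes rose, and genes of skeletal muscle fell. Cxcl9, a chemokine for activated T cells, rose by 9.82 ± 1.19 log2 units over control skin (n = 3 arrays per group). Stfa3, Csta3, Cstdc6 and Stfa1, cysteine protease inhibitors of the stefin family, rose by 9.10 ± 0.76, 8.99 ± 0.73, 8.74 ± 0.75 and 8.68 ± 0.88. Sprr1b, a precursor of the cornified envelope, rose by 8.95 ± 0.61, S100a8, a calcium-binding alarmin of neutrophils and stressed keratinocytes, by 8.81 ± 0.78, and the gasdermin Gsdmc by 8.72 ± 0.66. The genes with the deepest falls all belong to muscle: Atp2a1, the calcium pump of fast fibres, fell by 10.22 ± 1.02, Tnnt3, a fast troponin, by 9.54 ± 0.82, Actn3 by 9.41 ± 0.80 and the myosin gene Myh4 by 9.36 ± 1.07. Titin (Ttn), calsequestrin (Casq1), muscle glycogen phosphorylase (Pygm) and nebulin (Neb) changed by -10.03, -9.67, -9.63 and -9.50. For each of these 16 genes the 3 oxazolone arrays all lay on 1 side of the 3 control arrays.

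By limma with Benjamini-Hochberg adjustment, 2904 of 30142 genes were higher and 2085 lower in oxazolone than in control skin, 1376 and 1011 of them by at least 2-fold, and 10277 genes had an unadjusted p under 0.05. The arrays of both groups did not overlap for 32.8% of genes, where chance gives 10%. After quantile renormalisation the counts were 2127 and 2937, so the excess of higher genes depends on the scaling. Leaving out 1 array also changed the counts. The higher count became 1102, 1153 and 4749 without control arrays 1, 2 and 3, 1362, 1674 and 1456 without oxazolone arrays 1, 2 and 3, and 1737 without urushiol array 3. The lower count became 1005, 974 and 3270 without control arrays 1, 2 and 3, and 1115, 1157 and 1004 without oxazolone arrays 1, 2 and 3. Of the main calls, 93.7% were also made without control array 3, but 40.2% and 41.0% without control arrays 1 and 2, and 45.4% to 52.4% without an oxazolone array.

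Interferon genes rose as a group. In the type 1 immunity list, 10 of 21 measured genes rose, 2 fell and 9 did not pass, with a median of 0.79, and adjusted over the list alone 12 rose and 2 fell. The competitive gene list test camera gave an adjusted p = 0.00194 for it, and an adjusted p = 0.4 with an estimated correlation. Besides Cxcl9, Gbp2, an interferon-induced GTPase, rose by 7.23 ± 0.68, Cxcl10 by 6.86 ± 0.66 and the cytotoxic granule protease Gzmb by 4.71 ± 0.92. Ifng, the gene of interferon gamma itself, rose by 2.75 ± 0.31 (adjusted p = 0.0028). The 2 genes that fell were Il12rb2, a receptor chain for interleukin 12, by 3.10 ± 0.30, and Ifngr1, a receptor chain for interferon gamma, by 1.03 ± 0.28. In the type I interferon list 15 of 18 genes rose and 3 did not pass, and all 18 rose adjusted over the list alone. Its median was 2.91, with an adjusted p = 1.53e-09 by camera and an adjusted p = 0.318 with an estimated correlation. Examples are the antiviral genes Ifit1 at 6.66 ± 0.65, Rsad2 at 5.79 ± 0.91, Oas1a at 4.61 ± 0.52 and Mx1 at 4.56 ± 0.52. Without control array 3, 9 type 1 genes rose and 2 fell, and 13 type I interferon genes rose. The calls of Gzmb and Ifngr1 were lost without 3 and 7 of the 9 arrays taken singly, at adjusted p up to 0.062 (control array 1) and 0.138 (control array 2).

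Regulatory and checkpoint molecules moved with them: 9 of 15 rose and 6 did not pass, 10 adjusted over the list alone (camera adjusted p = 1.81e-05, and adjusted p = 0.28 with an estimated correlation). Cd274, which encodes the checkpoint ligand PD-L1, rose by 5.17 ± 0.50, the receptor gene Havcr2 by 2.74 ± 0.20 and Il2ra by 1.41 ± 0.31. Of 15 T cell markers 3 rose, namely Icos (2.97 ± 0.54), Cd8a (2.02 ± 0.55) and Cd5 (0.66 ± 0.11), and 1 fell, the receptor chain gene Cd3e (-1.10 ± 0.24). Adjusted over the list alone, 7 T cell markers rose and 1 fell. Camera gave the T cell list an adjusted p = 0.0447, and an adjusted p = 0.573 with an estimated correlation. The call was lost without control array 3 (0.17), oxazolone array 1 (0.106) or 3 (0.122) and urushiol array 1 (0.0634) or 2 (0.051), and its adjusted p ran from 0.000521 to 0.573 over all alternatives. Among the genes, the calls of Il2ra, Icos, Cd3e and Cd8a were lost without 3, 2, 3 and 8 arrays taken singly, at adjusted p up to 0.0784, 0.0534, 0.0798 and 0.123, each highest without control array 1 or 2.

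Genes of the interleukin 1 and interleukin 17 pathways and of neutrophils rose. Of 20 inflammasome, IL-1 and NF-kB genes 13 rose and 7 did not pass, 16 adjusted over the list alone (camera adjusted p = 5.75e-07, and adjusted p = 0.211 with an estimated correlation). Il1b rose by 8.11 ± 0.39, Ptgs2, which encodes the inducible cyclooxygenase, by 6.32 ± 0.69, Il1a by 3.73 ± 0.54 and Tnf by 1.66 ± 0.42 (adjusted p = 0.0387). In the type 17 list 11 of 21 genes rose and 10 did not pass, 12 adjusted over the list alone (camera adjusted p = 9.17e-06, and adjusted p = 0.211 with an estimated correlation). Il24 rose by 7.88 ± 0.49, the epidermal IL-36 genes listed as Il1f6 and Il1f8 by 5.62 ± 0.59 and 4.66 ± 0.59, the defensin gene Defb14 by 4.78 ± 0.65 and Il6 by 4.40 ± 0.55. Il17a itself stood at -0.02 ± 0.04 (adjusted p = 0.786). Of 19 neutrophil markers 13 rose and 6 did not pass, 14 adjusted over the list alone (camera adjusted p = 6.95e-08, and adjusted p = 0.211 with an estimated correlation), with S100a9 at 8.23 ± 0.61, the chemokine gene Cxcl2 at 6.80 ± 0.50 and Trem1 at 5.20 ± 0.60. Among 20 monocyte and macrophage markers 8 rose and 12 did not pass, and adjusted over the list alone 10 rose and 1 fell. The chemokine genes Ccl7, Ccl12 and Ccl2 rose by 4.14 ± 0.70, 4.08 ± 0.53 and 3.70 ± 0.51, and camera gave the list an adjusted p = 0.000721, and an adjusted p = 0.397 with an estimated correlation. Without control array 3, 13 IL-1, 10 type 17 and 13 neutrophil genes rose. The call of Tnf was lost without 6 arrays taken singly, control arrays 1 and 2, oxazolone arrays 1 and 3 and urushiol arrays 2 and 3, at adjusted p up to 0.116 (control array 1).

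Type 2 and mast cell genes moved both ways. In the type 2 list 7 of 22 genes rose, 2 fell and 13 did not pass, and adjusted over the list alone 11 rose and 2 fell. Il4ra, a receptor chain for interleukins 4 and 13, rose by 4.06 ± 0.29, the alarmin Il33 by 4.04 ± 0.29 and the arginase gene Arg1 by 3.63 ± 0.59, while Retnla, a product of alternatively activated macrophages, fell by 4.35 ± 0.90 and the chemokine receptor gene Ccr4 by 2.66 ± 0.21. The eosinophil chemokine gene Ccl11 rose by 0.94 ± 0.21, whereas Ccl17 (0.97 ± 0.34), Il4 (0.40 ± 0.13), Il13 (0.82 ± 0.26) and Tslp (0.37 ± 0.53) did not pass, at adjusted p = 0.0932, 0.0772, 0.0739 and 0.66. Camera gave the type 2 list an adjusted p = 0.0326, and an adjusted p = 0.318 with an estimated correlation. The call was lost without control array 3 (0.18) or oxazolone array 3 (0.0771), in a range of 0.00157 to 0.318 over all alternatives. The calls of Retnla and Ccl11 were each lost without 4 arrays taken singly, at adjusted p up to 0.0756 (control array 2) and 0.0758 (control array 1). Of 17 mast cell, basophil and eosinophil markers 4 rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0592, and adjusted p = 0.533 with an estimated correlation). Hdc, the enzyme that makes histamine, rose by 4.98 ± 0.38, and the mast cell receptor gene Mrgprb2 fell by 3.02 ± 0.17, while the receptor chain gene Fcer1a stood at 1.32 ± 0.37 and did not pass, though it did under some alternatives, among them without urushiol array 2 (0.0162). Camera called the mast cell list without control array 2 (0.0488), oxazolone array 2 (0.0254) or urushiol array 1, 2 or 3 (0.0495, 0.042 and 0.0458), in a range of 0.0059 to 0.533 over all alternatives.

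Among 39 measured itch mediators and receptors 15 rose, 3 fell and 21 did not pass, and adjusted over the list alone 19 rose and 3 fell (camera adjusted p = 0.00141, and adjusted p = 0.184 with an estimated correlation). The kallikrein protease genes Klk6 and Klk13 rose by 6.72 ± 0.55 and 5.99 ± 0.67, and Nppb, the natriuretic peptide gene known as an itch transmitter of sensory neurons, by 4.25 ± 0.53. Tph1, the enzyme that makes serotonin outside the brain, rose by 1.01 ± 0.18 (adjusted p = 0.0142). The 3 genes that fell were Il31ra (-1.77 ± 0.26), the serotonin transporter gene Slc6a4 (-1.03 ± 0.19) and the opioid precursor gene Penk (-0.61 ± 0.14). Il31, Edn1, Tac1, Trpa1 and Trpv1 stood at -0.11, 0.54, 0.12, 0.00 and 0.07 and did not pass, at adjusted p = 0.162, 0.0922, 0.249, 1 and 0.284. The transcripts of Trpa1, Trpv1 and Tac1 are known from sensory neurons, whose cell bodies lie outside the skin. The calls of Tph1 and Penk were lost without 1 and 6 arrays taken singly, at adjusted p up to 0.0535 (control array 1) and 0.0877 (oxazolone array 1), and Edn1 was called without control array 3 (0.0346).

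Keratinocyte stress genes rose, though whole skin cannot tell epidermis from neutrophils as their source. Of 22 keratinocyte stress genes 21 rose, and all 22 did adjusted over the list alone, with a median of 6.07 (camera adjusted p = 3.6e-16, and adjusted p = 0.211 with an estimated correlation). Besides the genes named above, the stefin Stfa2 rose by 8.37 ± 0.45, and 20 stress genes rose without control array 3. Of 31 differentiation and barrier genes 10 rose, 3 fell and 18 did not pass, and adjusted over the list alone 12 rose and 3 fell. Tgm3, a transglutaminase of the cornified envelope, rose by 6.83 ± 0.63 and the filaggrin relative Rptn by 6.27 ± 0.41, while the keratin gene Krt77 fell by 8.11 ± 1.05, Lce1m by 4.99 ± 0.35 and Flg2 by 3.78 ± 0.36. Filaggrin itself (Flg) stood at 2.41 ± 0.73 (adjusted p = 0.063) and passed without control array 3 (0.00261). Camera gave the differentiation list an adjusted p = 0.0284, and an adjusted p = 0.624 with an estimated correlation. It was lost without control array 1 (0.0527) or 2 (0.0892) or oxazolone array 3 (0.186), in a range of 0.00159 to 0.624 over all alternatives. NRF2, glutathione and xenobiotic genes moved both ways, with 7 of 19 up and 3 down, 9 and 3 adjusted over the list alone (camera adjusted p = 0.0592, and adjusted p = 0.28 with an estimated correlation). The cystine transporter gene Slc7a11 rose by 5.64 ± 0.49 and Gsta4 by 5.30 ± 0.52, and Gstm1 fell by 3.93 ± 0.49. Camera called the NRF2 list after quantile renormalisation (0.011) and median centring (0.00995), and without oxazolone array 1 (0.0254) or 2 (0.0477), in a range of 0.00995 to 0.28 over all alternatives.

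Hair follicle, cell division, melanocyte and muscle genes moved with the position of control array 3. Of 26 hair follicle genes 1 rose over all genes tested, the hair keratin Krt84 (0.90 ± 0.23), against 20 adjusted over the list alone and 24 without control array 3. The members with the biggest differences, Krtap8-1 (8.16 ± 2.40) and Krt71 (6.71 ± 2.52), did not pass, and camera gave an adjusted p = 4.27e-05, and an adjusted p = 0.533 with an estimated correlation. Both passed without control array 3 (0.00257 and 0.000398). Of 21 cell division genes 2 rose, Rrm2 (1.75 ± 0.48) and Cdk1 (1.39 ± 0.37), against 20 adjusted over the list alone and 21 without control array 3 (camera adjusted p = 8.85e-05, and adjusted p = 0.533 with an estimated correlation), and the list call was lost with the hair follicle score as a covariate (0.583). None of the 8 melanocyte markers passed by limma, over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05, and 4 passed without control array 3. Tyrp1 and Dct stood at 4.25 ± 1.48 and 3.53 ± 1.43 and passed without control array 3 (0.00434 and 0.00684), and camera gave the list an adjusted p = 0.0414, and an adjusted p = 0.573 with an estimated correlation. That call was lost without control array 1 (0.0943) or 2 (0.0892), oxazolone array 2 (0.15) or 3 (0.0771), and urushiol array 1 (0.0572) or 2 (0.051), in a range of 0.00469 to 0.573 over all alternatives. All 15 muscle markers fell, with a median of -8.35, also without control array 3 (camera adjusted p = 1.2e-19, and adjusted p = 0.211 with an estimated correlation), and so did all 15 adjusted over the list alone. The calls of Krt84, Rrm2 and Cdk1 were lost without 7, 8 and 8 arrays taken singly, at adjusted p up to 0.119, 0.147 and 0.133, each highest without control array 1 or 2.

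By list medians, other resident tissue changed less than muscle. Of 11 adipocyte markers 9 fell, 10 adjusted over the list alone, among them the carbonic anhydrase gene Car3 at -3.57 ± 0.26 and the lipoprotein lipase gene Lpl at -2.60 ± 0.30 (camera adjusted p = 8.82e-10, and adjusted p = 0.211 with an estimated correlation). Of 9 Schwann cell and nerve markers 3 fell, 4 adjusted over the list alone, with Cdh19 at -1.54 ± 0.26 and Pmp22 at -1.44 ± 0.19 (camera adjusted p = 0.00791, and adjusted p = 0.211 with an estimated correlation). Of 21 sebaceous and lipid synthesis genes 4 fell, also adjusted over the list alone, including the desaturase gene Scd3 by 3.88 ± 0.41 and the fatty acid synthase gene Fasn by 2.30 ± 0.35 (camera adjusted p = 0.0164, and adjusted p = 0.573 with an estimated correlation). The sebaceous call was lost without control array 3 (0.0733) or oxazolone array 1 (0.439), where the median turned to 0.04 and 0.22, in a range of 0.000307 to 0.573 over all alternatives. The matrix list split, with 6 of 19 genes up and 4 down both over all genes and adjusted over the list alone. The collagenase gene Mmp13 rose by 8.55 ± 0.67 and Tnc, the gene of the matrix protein tenascin C, by 8.18 ± 0.84, and the collagen genes Col1a1 and Col1a2 fell by 2.13 ± 0.58 and 2.21 ± 0.48. Its median was -0.10 and its mean 1.29, and camera pointed up without a call (adjusted p = 0.895). Endothelial genes (4 up and 1 down of 16, 5 and 1 adjusted over the list alone) and dendritic cell markers (4 up and 1 down of 18, 7 and 2 adjusted over the list alone) were not called by camera, at adjusted p = 0.994 and 0.895. Pdpn (2.30 ± 0.24) and the adhesion gene Sele (1.88 ± 0.25) rose in the first list, and the costimulatory gene Cd80 (2.57 ± 0.17) and Fscn1 (1.31 ± 0.25) in the second. Both lists had a negative median (-0.06 and -0.02) and a positive mean (0.26 and 0.23), with camera pointing down. Of 11 B cell markers 1 fell, the immunoglobulin gene Ighm by 1.95 ± 0.29, also adjusted over the list alone (camera adjusted p = 0.471), with a median of 0.02 and a mean of -0.16. Of 12 immediate early and heat shock genes 1 rose, Ier3 by 3.31 ± 0.35, also adjusted over the list alone, and Fosb stood at -1.77 ± 1.26 (camera adjusted p = 0.58). Alas2 and Slc4a1, the 2 measured erythrocyte markers, stood at -0.20 ± 0.16 and 0.08 ± 0.05 in oxazolone and at -0.33 ± 0.16 and 0.04 ± 0.05 in urushiol skin, and did not pass. The calls of Col1a1, Col1a2 and Fscn1 were lost without 7, 4 and 4 arrays taken singly, at adjusted p up to 0.133 (oxazolone array 2), 0.0783 (control array 1) and 0.0631 (control array 2).

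**Figure D2:**
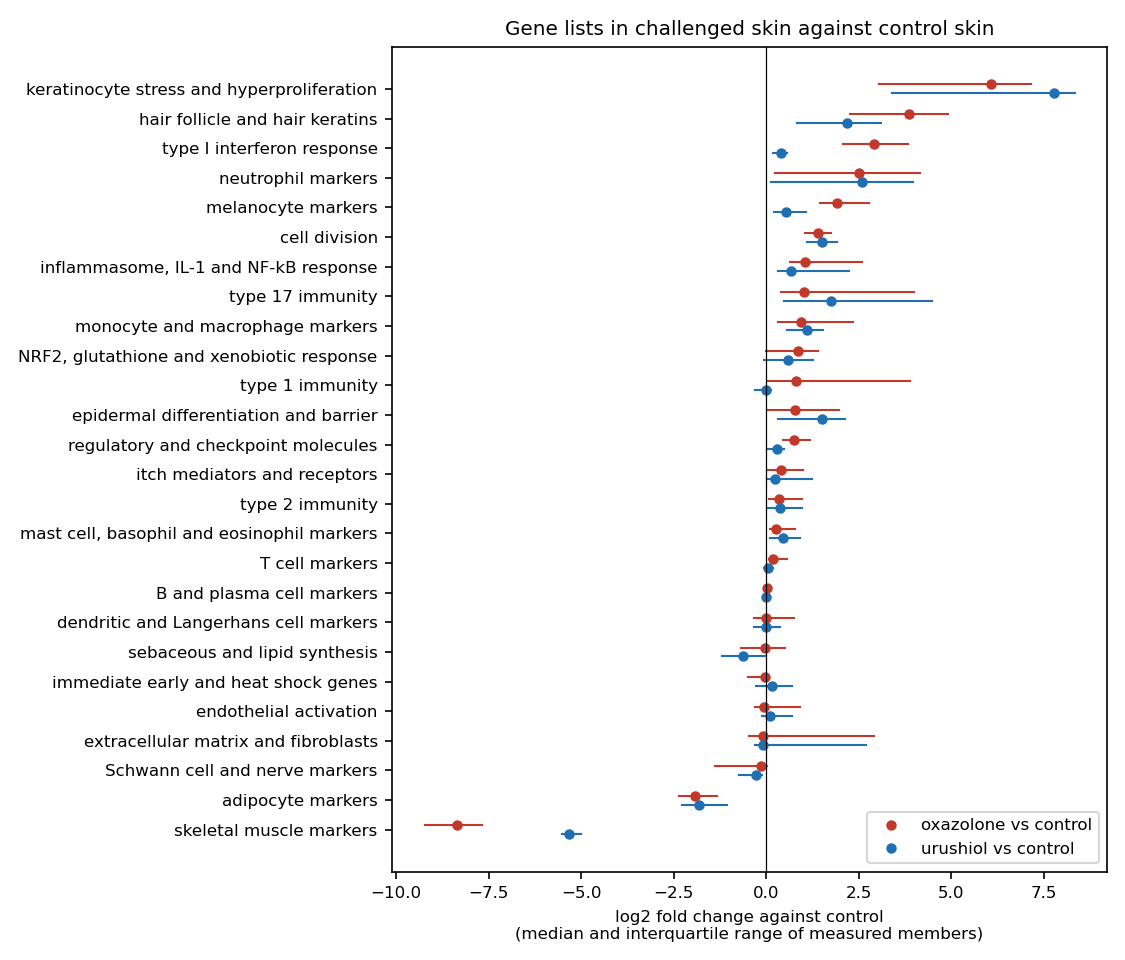
Median log2 fold change of the measured members of 26 gene lists against control skin (points) with the interquartile range of the members (lines), for oxazolone (red) and urushiol (blue). The type I interferon list has a median of 2.91 in oxazolone and 0.39 in urushiol skin, and the muscle list -8.35 and -5.34.

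In urushiol-challenged skin, calprotectin, stefins and cornified envelope genes rose, and epidermal and muscle genes fell. S100a8 rose by 10.58 ± 0.78 over control skin (n = 3 arrays per group) and its partner S100a9 by 9.98 ± 0.61. The stefin genes Csta3, Stfa3, Stfa1, Stfa2l1 and Cstdc6 rose by 9.90 ± 0.73, 9.61 ± 0.76, 9.48 ± 0.88, 9.47 ± 0.54 and 9.16 ± 0.75, and Sprr1b by 9.78 ± 0.61. Krt77 fell by 10.35 ± 1.05, the deepest fall of the named genes. Skint5 and Skint6, members of a keratinocyte family related to butyrophilins, fell by 7.72 ± 0.59 and 6.52 ± 0.67, the Mas-related receptor gene Mrgprb3 by 6.60 ± 0.19, and the muscle genes Casq1, Mstn, Klhl31 and Mybpc2 by 6.81 ± 0.75, 6.79 ± 1.20, 6.72 ± 0.95 and 6.50 ± 0.85. For each of these 16 genes the 3 urushiol arrays all lay on 1 side of the 3 control arrays.

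By limma, 3003 of 30142 genes were higher and 1939 lower in urushiol than in control skin, 1378 and 878 of them by at least 2-fold, and 9695 genes had an unadjusted p under 0.05. Arrays did not overlap for 32.9% of genes, against 10% by chance. After quantile renormalisation the counts were 2297 and 2341. The higher count became 1343, 1327 and 4566 without control arrays 1, 2 and 3, and 1326 and 1426 without urushiol arrays 1 and 3. The lower count became 985, 890 and 3089 without control arrays 1, 2 and 3, and 863, 1125 and 1003 without urushiol arrays 1, 2 and 3. Of the main calls, 93.3% were also made without control array 3, but 44.8% and 43.1% without control arrays 1 and 2, and 43.4% to 60.1% without a urushiol array.

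The keratinocyte stress list rose most in urushiol skin. All 22 of 22 keratinocyte stress genes rose, also adjusted over the list alone, with a median of 7.76 (camera adjusted p = 3.97e-19, and adjusted p = 0.206 with an estimated correlation). Stfa2 rose by 9.04 ± 0.45, and all 22 stress genes rose without control array 3 too. Of 31 differentiation and barrier genes 16 rose and 3 fell, 21 and 3 adjusted over the list alone (camera adjusted p = 9.47e-05, and adjusted p = 0.48 with an estimated correlation). Tgm3 rose by 8.11 ± 0.63, Rptn by 7.46 ± 0.41 and Flg by 2.87 ± 0.73, and Lce1m fell by 5.22 ± 0.35 and Flg2 by 4.18 ± 0.36. The call of Flg (adjusted p = 0.0391) was lost without any single one of 8 arrays, all but control array 3, at adjusted p = 0.0636 to 0.126. In the NRF2 list 7 of 19 genes rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.101, and adjusted p = 0.315 with an estimated correlation, but 0.042 after quantile renormalisation and 0.0197 after median centring), with Slc7a11 at 6.31 ± 0.49 and the aldo-keto reductase gene Akr1b8 at 4.02 ± 0.33.

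Interleukin 17 and interleukin 1 pathway genes rose in urushiol skin as well. Of 21 type 17 genes 12 rose and 9 did not pass, 16 adjusted over the list alone, with a median of 1.75 (camera adjusted p = 1.2e-07, and adjusted p = 0.206 with an estimated correlation). Il1f6 rose by 7.90 ± 0.59, Il24 by 6.85 ± 0.49, Il1f8 by 5.48 ± 0.59, Defb14 by 5.43 ± 0.65 and Il6 by 2.93 ± 0.55, while Il17a stood at 0.02 ± 0.04. The call of Il6 was lost without control array 1 (0.0555) or 2 (0.0569) or urushiol array 1 (0.0541). Of 20 inflammasome, IL-1 and NF-kB genes 8 rose, 11 adjusted over the list alone (camera adjusted p = 6.62e-05, and adjusted p = 0.315 with an estimated correlation), among them Il1b by 7.77 ± 0.39, Ptgs2 by 6.59 ± 0.69 and Il1a by 4.24 ± 0.54, and Tnf stood at 1.29 ± 0.42 (adjusted p = 0.0808). Neutrophil markers rose in 12 of 19 cases, 13 adjusted over the list alone (camera adjusted p = 1.71e-07, and adjusted p = 0.245 with an estimated correlation), with Cxcl2 at 6.82 ± 0.50 and Trem1 at 5.57 ± 0.60. Monocyte and macrophage markers rose in 6 of 20 cases, 12 adjusted over the list alone (camera adjusted p = 0.00049, and adjusted p = 0.439 with an estimated correlation), with the lipopolysaccharide coreceptor gene Cd14 at 2.96 ± 0.51 and Ccl12 at 2.60 ± 0.53. Without control array 3, 12 type 17, 8 IL-1 and 10 neutrophil genes rose, and 1 IL-1 gene fell. The call of Ccl12 was lost without 4 arrays taken singly, at adjusted p up to 0.0668 (control array 1), and Tnf was called without oxazolone array 1 (0.0344).

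Interferon genes were not called against control in urushiol skin. In the type 1 list 1 of 21 genes changed, Il12rb2, which fell by 4.66 ± 0.30, also adjusted over the list alone (camera adjusted p = 0.119). Cxcl9, Gbp2, Cxcl10 and Ifng stood at 0.52 ± 1.19, -0.45 ± 0.68, 0.53 ± 0.66 and 0.04 ± 0.31, and Ifng had an adjusted p = 0.968. None of the 18 type I interferon genes passed by limma, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. The median was 0.39 (camera adjusted p = 0.738), with Oas1a at 0.89 ± 0.52, Ifit1 at 0.84 ± 0.65 and Usp18 at -0.79 ± 0.51. With the 6 arrays of the comparison fitted alone, camera called this list (adjusted p = 0.00864), in a range of 0.00864 to 0.934 over all alternatives. The type 1 list was called, pointing down, without oxazolone array 3 (0.0442) or urushiol array 1 (0.0439), in a range of 0.0439 to 0.729. Of 15 regulatory molecules 1 rose, Havcr2 by 1.48 ± 0.20, also adjusted over the list alone, and Cd274 stood at 1.69 ± 0.50 (camera adjusted p = 0.116). This list was called without oxazolone array 3 (0.0119), in a range of 0.00289 to 0.729 over all alternatives. Among T cell markers 2 of 15 rose, Cd4 (0.88 ± 0.15) and Cd5 (0.67 ± 0.11), and 2 fell, Cd3e (-1.87 ± 0.24) and Cd3g (-1.25 ± 0.29), with 3 and 2 adjusted over the list alone. Camera pointed down for the T cell list, without a call (adjusted p = 0.748), where median and mean were both 0.03. The call of Cd3g was lost without 7 arrays taken singly, at adjusted p up to 0.0938 (control array 1), and Cd274 and Oas1a were called without oxazolone array 3 (0.0165 and 0.0323).

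Type 2, mast cell and itch genes again moved both ways. Of 22 type 2 genes 7 rose and 2 fell, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.315 with an estimated correlation). Arg1 rose by 4.58 ± 0.59 and Il33 by 4.44 ± 0.29, and Retnla and Ccr4 fell by 3.96 ± 0.90 and 3.61 ± 0.21. Tslp, an epithelial cytokine that acts on dendritic cells and sensory neurons, rose by 3.02 ± 0.53 (adjusted p = 0.012). Ccl11, Ccl17, Il4 and Il13 stood at 0.73 ± 0.21, 0.51 ± 0.34, 0.45 ± 0.13 and 0.65 ± 0.26 and did not pass. Of 17 mast cell, basophil and eosinophil markers 5 rose and 1 fell, 6 and 1 adjusted over the list alone, with Hdc at 5.17 ± 0.38, Fcer1a at 1.49 ± 0.37 and Mrgprb2 at -2.30 ± 0.17 (camera adjusted p = 0.0207, and adjusted p = 0.467 with an estimated correlation). Without control array 3 the type 2 and mast cell lists were no longer called (0.175 and 0.132), in ranges of 0.00546 to 0.315 and 0.00328 to 0.467 over all alternatives. Of 39 itch mediators and receptors 12 rose and 3 fell, 15 and 3 adjusted over the list alone (camera adjusted p = 0.00101, and adjusted p = 0.158 with an estimated correlation). Klk13 rose by 7.83 ± 0.67, Klk6 by 7.69 ± 0.55 and Nppb by 3.91 ± 0.53, and Il31ra, Slc6a4 and Penk fell by 2.22 ± 0.26, 0.92 ± 0.19 and 0.80 ± 0.14. Tph1, Il31, Edn1, Tac1, Trpa1 and Trpv1 stood at 0.48, 0.03, 0.25, 0.13, -0.00 and 0.03 and did not pass. The calls of Retnla, Fcer1a and Slc6a4 were lost without 6, 8 and 2 arrays taken singly, at adjusted p up to 0.0962 (control array 2), 0.124 (control array 2) and 0.0589 (urushiol array 1), and Tph1 was called without oxazolone array 1 (0.00757) and Ccl11 without control array 2 (0.0484).

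Resident tissue lists moved as follows in urushiol skin. Of 15 muscle markers 13 fell, 15 adjusted over the list alone and 15 without control array 3, with a median of -5.34 (camera adjusted p = 1.45e-14, and adjusted p = 0.206 with an estimated correlation). Actn3 fell by 6.49 ± 0.80 and Atp2a1 by 5.62 ± 1.02, and the call of Atp2a1 was lost without control array 1 (0.0521) or 2 (0.0536) or urushiol array 1 (0.0541). Of 26 hair follicle genes 1 rose, Krt84 (1.11 ± 0.23), also adjusted over the list alone, and 15 did without control array 3, with Krtap8-1 at 5.97 ± 2.40 (camera adjusted p = 0.0215, and adjusted p = 0.782 with an estimated correlation). The hair list was not called without control array 1 (0.205) or 2 (0.153) or urushiol array 2 (0.0905), in a range of 2.97e-06 to 0.782 over all alternatives. Of 21 cell division genes 3 rose, Rrm2 (2.11 ± 0.48), Mcm4 (1.91 ± 0.49) and Mcm3 (1.56 ± 0.42), against 20 adjusted over the list alone and 21 without control array 3 (camera adjusted p = 2.42e-05, and adjusted p = 0.534 with an estimated correlation). None of the 8 melanocyte markers passed by limma, over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 2 called without control array 3, and Tyrp1 stood at 2.07 ± 1.48 (camera adjusted p = 0.825). Of 11 adipocyte markers 8 fell, also adjusted over the list alone, with Car3 at -2.69 ± 0.26 and Pnpla2 at -2.52 ± 0.40 (camera adjusted p = 1.42e-08, and adjusted p = 0.206 with an estimated correlation). Nerve markers fell in 3 of 9 cases, also adjusted over the list alone, with Cdh19 at -1.20 ± 0.26 (camera adjusted p = 0.00153, and adjusted p = 0.206 with an estimated correlation). Sebaceous genes fell in 5 of 21 cases, also adjusted over the list alone, with Scd3 at -4.43 ± 0.41 and Elovl5 at -2.56 ± 0.51 (camera adjusted p = 0.000242, and adjusted p = 0.467 with an estimated correlation). The calls of Krt84, Rrm2, Mcm4 and Mcm3 were lost without 3, 8, 8 and 8 arrays taken singly, at adjusted p up to 0.0691, 0.0914, 0.132 and 0.137, each highest without control array 1 or 2. Those of Cdh19 and Elovl5 were lost without 5 and 4 arrays, at adjusted p up to 0.0854 (control array 2) and 0.0634 (urushiol array 1), while Krtap8-1 and Tyrp1 were called without control array 3 (0.00607 and 0.0234).

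The remaining urushiol lists were not called by camera. Of 19 matrix genes 5 rose and 3 fell, 7 and 4 adjusted over the list alone, with Tnc at 7.57 ± 0.84 and Mmp13 at 7.19 ± 0.67, a median of -0.09 and a mean of 1.14 (adjusted p = 0.738). Endothelial genes rose in 2 and fell in 1 of 16 cases, the same numbers adjusted over the list alone, with Pdpn at 1.85 ± 0.24 and Ackr1 at -1.78 ± 0.35 (adjusted p = 0.738). Dendritic cell markers rose in 2 and fell in 2 of 18 cases, 3 and 4 adjusted over the list alone, with Cd80 at 2.13 ± 0.17 and Fscn1 at 1.46 ± 0.25, a median of -0.01 and a mean of 0.06, and camera pointing down (adjusted p = 0.573). Ighm fell by 1.59 ± 0.29 as 1 of 11 B cell markers, also adjusted over the list alone (adjusted p = 0.342), and Ier3 rose by 3.86 ± 0.35 as 1 of 12 immediate early and heat shock genes, also adjusted over the list alone (adjusted p = 0.738). The immediate early list was called without control array 2 (0.0228), in a range of 0.0228 to 0.985 over all alternatives. The calls of Ackr1 and Ighm were lost without 4 and 1 arrays taken singly, at adjusted p up to 0.066 (control array 2) and 0.0512 (control array 1).

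**Figure D3:**
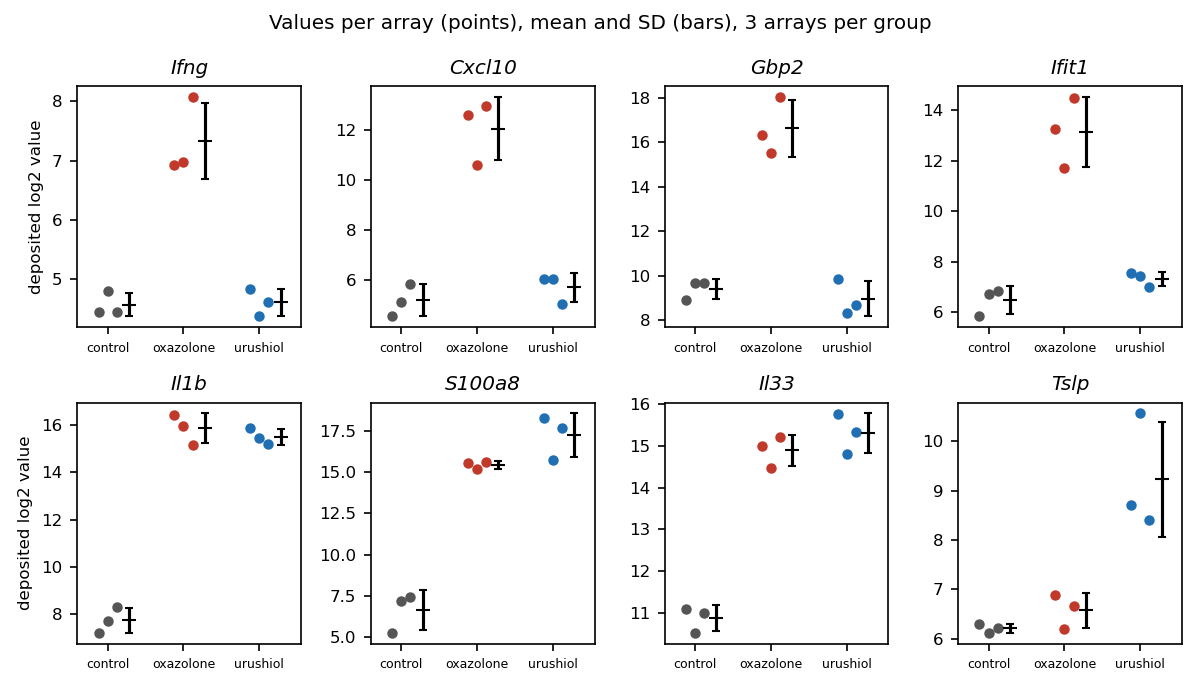
Deposited log2 values of 8 genes on each array (points), with the mean and SD of the 3 arrays of each group (bars); the vertical axes start at different values. Ifng, Cxcl10, Gbp2 and Ifit1 lie higher on all 3 oxazolone arrays than on all 3 urushiol arrays, Il1b and Il33 lie at similar levels in both groups, and the urushiol difference from control is 3.02 for Tslp.

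The direct comparison of the allergens, at the same strength, volume and schedule, called few genes. The interferon-induced gene Gbp2 was lower in urushiol than in oxazolone skin by a log2 difference of -7.68 ± 0.68, and Stat4, a transcription factor of interleukin 12 signalling, and Rgs16, a regulator of G protein signalling, by -0.77 ± 0.07 and -1.29 ± 0.11 (n = 3 arrays per group). Smpd1, the acid sphingomyelinase, and the protocadherin gene Pcdhb17 were higher, by 0.87 ± 0.08 and 0.82 ± 0.07. These 2 higher and 3 lower genes were the calls by limma among 30142 genes, each at an adjusted p = 0.0486, and 1772 genes had an unadjusted p under 0.05. Arrays of the allergens did not overlap for 9.74% of genes, where chance gives 10%. The 5 calls depended on the fit. They were kept without dim genes, with cluster means, after either rescaling and with array weights. The fit of the 6 challenged arrays alone called 2 higher and 0 lower genes (2080 at an unadjusted p under 0.05), and the fit with the replicate number as a block, at the same log2 differences, called 0, and none of the 5 was called in either. Without control array 3 there were 7 higher and 0 lower calls, none of them among the 5. Without oxazolone array 2 there were 3 higher and 91 lower calls, without oxazolone array 3 there were 4 and 56, and without any 1 of the other 6 arrays there was none. The 5 calls were kept without oxazolone array 2 or 3 and lost without any other array, at adjusted p from 0.0526 (control array 3) to 0.375 (Gbp2 without urushiol array 3).

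Read as gene lists, the interferon difference was broad. All 18 type I interferon genes were lower in urushiol than in oxazolone skin adjusted over the list alone and none over all genes by limma, 18 had an unadjusted p under 0.05, and the median was -2.51. Camera gave an adjusted p = 4.29e-32, and an adjusted p = 0.16 with an estimated correlation, and the self-contained test fry an adjusted p = 0.0238. In the type 1 list 13 of 21 genes were lower adjusted over the list alone and 1, Gbp2, over all genes (camera adjusted p = 4.03e-20, and adjusted p = 0.16 with an estimated correlation, fry adjusted p = 0.0118). Cxcl9, Cxcl10, Ifit1, Irf1 and Ifng differed by -9.30 ± 1.19, -6.34 ± 0.66, -5.82 ± 0.65, -4.10 ± 0.44 and -2.71 ± 0.31, at adjusted p = 0.0991 for Cxcl9 and 0.0767 for the other 4, so none passed alone over all genes. Without oxazolone array 2, Cxcl10, Ifit1, Irf1, Ifng, Cd274 and Cd8b1 passed (0.0151, 0.0203, 0.0272, 0.0478, 0.0478 and 0.023), and without oxazolone array 3, Ifit1, Irf1, Ifng and Cd274 did (0.0346, 0.012, 0.012 and 0.0383). For all 18 type I interferon genes, and for 14 of 21 type 1 genes, the 3 oxazolone arrays lay apart from the 3 urushiol arrays, where chance gives 10%. Regulatory molecules were lower in 7 of 15 cases adjusted over the list alone, with Cd274 at -3.47 ± 0.50 and Havcr2 at -1.26 ± 0.20 (camera adjusted p = 8.44e-14, and adjusted p = 0.16 with an estimated correlation, fry adjusted p = 0.0417). T cell markers were lower in 5 of 15 cases adjusted over the list alone, with Cd8a at -1.76 ± 0.55 and Cd8b1 at -1.61 ± 0.48 (camera adjusted p = 1.19e-06, and adjusted p = 0.48 with an estimated correlation, fry adjusted p = 0.23). Fry called the type 1, type I interferon and regulatory lists alone, and without control array 3 the regulatory list was not called (0.0667).

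Muscle and epidermal lists differed in the other direction. Muscle markers were higher in urushiol than in oxazolone skin in 11 of 15 cases adjusted over the list alone, with a median of 2.89, and Atp2a1 differed by 4.61 ± 1.02 (camera adjusted p = 1.38e-19, and adjusted p = 0.18 with an estimated correlation, fry adjusted p = 0.0525). Fry called the muscle list without control array 3 (0.0134), and its camera adjusted p there, 3.36e-26, was the lowest of all lists. Differentiation genes were higher in 7 of 31 cases adjusted over the list alone, with a median of 0.36 and Tgm5 at 1.33 ± 0.30 (camera adjusted p = 9.73e-06, and adjusted p = 0.559 with an estimated correlation). In the keratinocyte stress list 1 gene was higher and 1 lower adjusted over the list alone, Ereg at 1.73 ± 0.34 and Itga5 at -0.68 ± 0.14, with a median of 0.89 and Lce3a at 2.42 ± 0.77 (camera adjusted p = 6.56e-05, and adjusted p = 0.559 with an estimated correlation). Tslp was 2.65 ± 0.53 higher in urushiol skin and did not pass (adjusted p = 0.276). Hair follicle and melanocyte genes were lower in urushiol skin, with medians of -1.58 and -1.44 and Krt32 and Tyrp1 at -1.81 ± 0.75 and -2.18 ± 1.48, though none was called adjusted over the list alone by limma, and 1 and 0 had an unadjusted p under 0.05. Camera called both (adjusted p = 2.67e-05 and 0.000193, and adjusted p = 0.622 and 0.559 with an estimated correlation). Type 17 genes pointed up (0.0203) and IL-1 and sebaceous genes pointed down (0.0332 and 0.0393, camera adjusted p), with 1 member (Defb4, 2.09 ± 0.42), 0 and 1 member (Dgat2, 1.02 ± 0.20, higher against its list) passing adjusted over the list alone, and with adjusted p = 0.59, 0.622 and 0.691 with an estimated correlation. Those 3 calls were not stable. With the 6 challenged arrays fitted alone the IL-1 and sebaceous calls were lost (0.0592 and 0.0634). Without oxazolone array 1 or urushiol array 1 the type 17 call was lost (0.267 and 0.222), and the IL-1 call without oxazolone array 1 or 3 or urushiol array 2 or 3 (0.324, 0.201, 0.253 and 0.0988). The sebaceous call was lost without oxazolone array 2 or 3 or urushiol array 1 or 2 (0.667, 0.637, 0.724 and 0.0914), and over all alternatives the 3 ranges were 0.00166 to 0.59, 1.89e-05 to 0.622 and 4.69e-08 to 0.724. In the fit of these 6 arrays with the replicate number as a block, the IL-1 call was also lost (0.15) and the immediate early list was called (0.0312). In the 9-array fit with the block the dendritic cell list (0.0611 without it) and the mast cell list (0.0738 without it) were also called, both at an adjusted p = 0.039, in ranges of 0.00286 to 0.559 and 0.00117 to 0.622 over all alternatives.

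Camera called neither these 2 lists nor 12 others between the allergens. Those 12 were immediate early genes (0.0586), adipocyte markers (0.0816), monocyte and macrophage markers (0.0899), NRF2 genes (0.225), cell division genes (0.608), type 2 genes (0.672), B cell markers (0.866), endothelial genes (0.866), matrix genes (0.866), neutrophil markers (0.908), nerve markers (0.908) and itch genes (0.967, all adjusted p). Adjusted over the list alone, 4 monocyte markers and 1 endothelial gene, the adhesion gene Icam1 (-0.82 ± 0.14), were lower in urushiol skin, type 2 genes split into 1 higher, Tslp, and 1 lower, Ccr4 (-0.94 ± 0.21), and no member of the other 9 passed by limma. Median, mean and test differed in sign for the type 2, B cell, neutrophil, monocyte, itch, cell division, endothelial and nerve lists, whose medians lay between -0.03 and 0.04. Single arrays again decided calls. Without oxazolone array 2 camera called the dendritic cell, monocyte, matrix and adipocyte lists (0.00286, 0.00286, 0.0395 and 0.0395), and without oxazolone array 3 the immediate early, neutrophil, adipocyte and monocyte lists (0.000565, 0.0146, 0.0409 and 0.0454). Without urushiol array 1 it called the monocyte, adipocyte and dendritic cell lists (0.00434, 0.0124 and 0.0173), without urushiol array 2 the mast cell list (0.00117), and without urushiol array 3 the immediate early list (0.0158). The immediate early list was also called without control array 1 (0.0295) or 2 (0.0127). Over all alternatives these adjusted p values ran from 0.00286 to 0.691 for monocyte markers, 0.000565 to 0.691 for immediate early genes, 0.0124 to 0.824 for adipocyte markers, 0.0146 to 0.963 for neutrophil markers and 0.0395 to 0.963 for matrix genes.

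**Figure D4:**
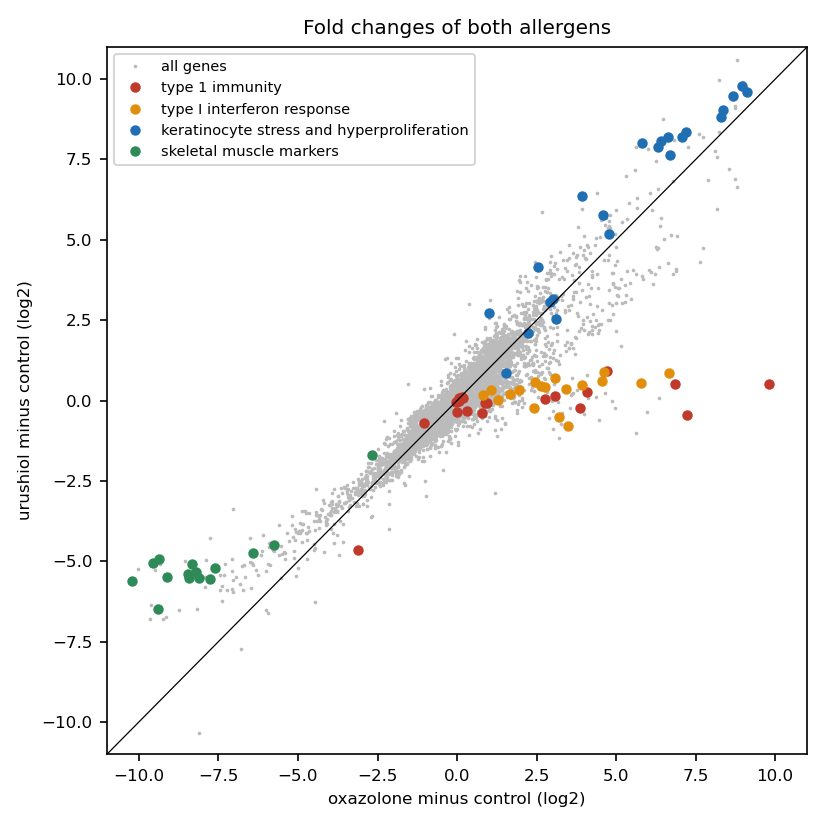
Log2 fold change against control skin of each of 30142 genes in oxazolone (horizontal) and urushiol skin (vertical), with 4 gene lists coloured and the line of equal change drawn. Type I interferon genes lie along the horizontal axis, with medians of 2.91 and 0.39, and keratinocyte stress genes near the line of equal change, with medians of 6.07 and 7.76.

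Most of the response was in the same direction for both allergens. Across genes, which are not independent replicates, the fold changes of the allergens correlated at 0.923, where unchanged groups simulated against the same 3 controls gave 0.693 ± 0.0145 (SD of 20 simulations). The covariance was 0.651, against 0.0437 in the simulation, a difference of 0.607. There were 2127 genes called higher in both and 1661 called lower in both, against 3.3 and 3.1 in the simulation and 289 and 134 for independent lists of the same lengths. The sign was the same for 84.1% of genes, against 69.4%. A single gene, the cytokine Il15, was called in opposite directions, at 0.14 ± 0.03 in oxazolone and -0.16 ± 0.03 in urushiol skin. These calls were lost without 8 and 5 arrays taken singly, at adjusted p up to 0.103 (control array 2) and 0.074 (urushiol array 3). A call in 1 comparison alone, as for 1200 genes with oxazolone and 1153 with urushiol, is not a test of a difference between the allergens. The 3 controls cannot be divided into parts of at least 2 arrays each, so part of the excess may come from the shared controls.

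A moderated F test over the 3 groups called 4241 genes. That count became 1509, 1540 and 7182 without control arrays 1, 2 and 3, 2715 and 2699 without oxazolone arrays 1 and 3, and 2694 and 2344 without urushiol arrays 1 and 3.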

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

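The tests of a mislabelled sample, of admixture, of dilution, of a single array behind the interferon difference and of a weaker response as a whole were chosen after the result was seen, as was the share over all 45 keratin-associated protein genes, and the others before.

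Clusters without a gene symbol, which no comparison above uses, carried signal as well. Of 33206 such clusters, 1387 were called higher and 942 lower in oxazolone than in control skin, and 1113 higher and 918 lower in urushiol than in control skin. That is 7.01% and 6.12% of them, against 10.5% and 9.71% of all clusters.

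Control array 3 lay apart from the other controls, toward challenged skin for hair follicle, cell division, melanocyte and muscle genes. A mislabelled challenged sample is argued against by 35 neutrophil and keratinocyte stress genes, which lay at a median position of 0.0699 between control arrays 1 and 2 (0) and challenged skin (1), while 20 cell division genes lay at 0.92 (in both sets, those at least 2-fold higher in challenged skin than in these 2 controls). Admixture of RNA from challenged skin would need 1 share for all genes, but the first set needed a median of 0.263% of challenged signal and the second 83.9%. Growing hair follicles in the piece of skin remain possible. Of 45 keratin-associated protein genes in no list, 37 (82.2%) lay at least 1 log2 unit above both other controls. The share was 86% of the 43 above the median of clusters on control array 3 itself, a choice that favours the explanation. The hair follicle list, already seen to be high on this array, holds genes of the same family. Their height therefore restates that finding and does not decide for hair growth. All these shares rest on a scale whose upper end no source used here explains, no label gives the hair cycle, and whether challenge or shaving started hair growth in the other groups stays untested.

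Skeletal muscle genes fell in both challenged groups. Dilution of resident tissue by inflamed tissue is argued against by the adipocyte list, whose median fall was at most 0.342 of the muscle median fall. Muscle damage with regeneration was tested with 7 genes of regenerating or denervated muscle. Of these, 1, Runx1 (1.81 ± 0.25 and 1.46 ± 0.25), was called higher, and 1 other was called lower in oxazolone skin. With muscle list medians of -8.35 and -5.34, little muscle signal was left in which regeneration could show. The test therefore cannot decide. Of 13 muscle genes in no list 92.3% were called lower in oxazolone skin and 84.6% in urushiol skin, the atrophy genes Trim63 and Fbxo32 among them, which restates the fall and does not decide for less muscle in the piece of skin, and the calls of Trim63 were lost without 5 and 8 arrays taken singly, at adjusted p up to 0.0721 (control array 1) and 0.107 (urushiol array 1). How deep the skin was taken is not given, so less muscle in the piece of skin and a loss of muscle in the animal cannot be told apart.

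Interferon genes were higher in oxazolone than in urushiol skin. A single array is argued against by list means, where the lowest oxazolone array lay above the highest urushiol array by 1.35 for the type 1 list and 1.71 for the type I interferon list. A weaker response to urushiol as a whole is argued against by the ratio of urushiol to oxazolone fold changes, which had a median of 1.06 over 44 neutrophil, IL-1 and keratinocyte stress genes (quartiles 0.926 and 1.15) and 0.127 over 17 type I interferon genes (quartiles 0.0933 and 0.17), all at least 2-fold higher in oxazolone than in control skin. Interferon gamma from CD8 T or natural killer cells may contribute. Of 12 cytotoxic lymphocyte genes in no list, 7 had all oxazolone above all urushiol arrays (0.6 by chance) and 0 the reverse. Of the 12, Klrd1 and Cd7 also mark epidermal T cells, and Cd7 lay below control. Cell recruitment, potency and timing stay untested.

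Other splits of the arrays bear on the counts. For each pair of groups, 1 of 10 splits, the real one, gave as many called genes, with 4989, 4942 and 5 in the order oxazolone, urushiol and allergens compared and 0 at most in the others, and 10 splits are too few for a share under 0.05. For the F test, 1 of 100 splits drawn from 280 gave as many genes, the real one with 4241, so chance can be excluded at that share. The highest of the others gave 3806, in a split that kept the 3 controls together and mixed the allergens, which points to control against challenge as the structure behind most calls. Among splits of the oxazolone and urushiol arrays that part all 3 number pairs, the other 3 called 0 genes.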

How the results depend on the processing

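The hair follicle covariate and 2 groups with the replicate block were chosen after the result was seen, and all others before. Counts (higher/lower, limma) are for oxazolone against control, urushiol against control and, where given, urushiol against oxazolone. They were 2904/2085, 3003/1939 and 2/3 in the 9-array fit. With 3 arrays per group, counts of calls depend on thresholds and single arrays, and a threshold cannot change a direction. Without detection calls, little can be said of dim genes.

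Leaving out 1 array at a time gave 1102 to 4749 higher and 974 to 3270 lower genes for oxazolone, 1326 to 4566 and 863 to 3089 for urushiol, and 0 to 7 and 0 to 91 between the allergens. The F test called 1509 to 7182 genes, and camera 15 to 20, 13 to 17 and 10 to 15 lists. The correlation of the allergens' fold changes ran from 0.902 to 0.944, and was 0.925 with the filter on dim genes, against 0.923.

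The F test called 2181 genes with unmoderated variances, 7452 with array weights, 1210 at an adjusted p under 0.01 and 1288 with the hair follicle covariate, against 4241. Why camera called 0 lists with an estimated correlation was not tested.

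Counts by setting were 1489/1289, 1684/1190 and 0/0 with unmoderated variances, and 4557/3131, 4932/3203 and 5/49 with array weights. They were 1262/936, 1449/875 and 2/0 with 2 groups only, which has fewer arrays. Other thresholds gave 1872/1215, 1775/1115 and 107/208 (unadjusted p under 0.05 with at least a 2-fold change), 672/594, 858/572 and 0/0 (adjusted p under 0.01), and 476/435, 539/323 and 0/0 (treat), fewer by construction in the last 2. The hair follicle covariate gave 336/387, 1387/1234 and 0/0. Between the allergens, limma also called 0/0 with trended and with robust variances. It called 4/31 with the filter on dim genes, which tests fewer genes, and 3/7 over all clusters for themselves. Where no construction is named, the cause was not tested.

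Scaling moved the balance of directions. The share of higher genes was 58.2% and 60.8% against control. Quantile renormalisation gave 2127/2937 (42%) and 2297/2341 (49.5%), so the excess of higher over lower genes did not hold for either allergen, and 2/3 between them. Median centring gave 2639/2483, 2757/2288 and 3/20, with 13% higher against 40%. The median fold change of all genes was 0.0567, 0.04 and -0.00333 in deposited values, -0.0141, -0.00852 and 0.0178 after quantile renormalisation, and -0.00333, -0.0133 and 0.00333 after centring.

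With the replicate number as a block in the 9-array fit, counts were 3088/1995 and 3267/1852, and 0/0 between the allergens. Same-numbered arrays of control and challenged skin do not all correlate best with their own number. Against control, the block ended the oxazolone T cell list call (adjusted p = 0.0506) and added the mast cell list (0.0321). It also moved 20 calls of named genes across the threshold, all at adjusted p between 0.0212 and 0.0852. Between the allergens, the block in the 9-array fit changed no call other than those given in the report. With 2 groups only and the block, counts were 464/244, 1/4 and 0/0 in fits with few degrees of freedom by construction. The oxazolone T cell (0.0891), melanocyte (0.089) and type 2 calls (0.0521) ended there, the mast cell list in oxazolone (0.015) and the regulatory list in urushiol skin (0.0191) were called, and between the allergens so were the dendritic cell (0.0312) and mast cell lists (0.0216), besides the changes given in the report.

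With the hair follicle score as a covariate, 5 list results turned. The medians changed sign for endothelial genes (0.63, called at 0.00425) and melanocyte markers (-0.070, call ended at 0.321) in oxazolone skin, melanocyte markers in urushiol skin (-0.71, called at 0.00546) and hair follicle genes in oxazolone skin (-0.19, call ended at 0.437). For hair follicle genes in urushiol skin the median fell from 2.17 to 0.044, the test pointed the other way and the call ended (0.26). The score is built from the hair follicle list, whose mean was 2.07 to 5.20 on challenged arrays and -1.53, -1.45 and 2.99 on controls. It can therefore remove challenge effects as well. The same covariate lowered the median of cell division genes in oxazolone skin from 1.39 to 0.15 and ended that call (0.583), and it ended the differentiation call there (0.199) and the hair follicle (0.47) and sebaceous calls (0.301) between the allergens. It also added calls of mast cell markers in oxazolone skin (0.0059), of endothelial genes in urushiol skin (0.0248), and of the cell division (9.34e-09), dendritic cell (0.00695), monocyte (0.00805) and endothelial lists (0.0455) between the allergens. For lists other than hair follicle the cause was not tested.

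Other settings also moved camera list calls. Rescaling by quantiles and by centring added the mast cell list in oxazolone skin (0.0392 and 0.0413) and the monocyte list between the allergens (0.016 and 0.042). Quantiles added the regulatory list in urushiol skin (0.0429). Centring added the dendritic cell, mast cell and immediate early lists between the allergens (0.0304, 0.0479 and 0.0479) and ended the oxazolone T cell (0.0501) and sebaceous calls (0.0578). The filter on dim genes ended the T cell (0.137), melanocyte (0.0644) and type 2 calls (0.109) in oxazolone and the type 2 call (0.187) in urushiol skin, and added the dendritic and mast cell lists (0.00853 and 0.0231) between the allergens. With 2 groups only the oxazolone T cell and melanocyte calls ended (0.0642 and 0.0668), and the mast cell list in oxazolone skin (0.0292), the regulatory list in urushiol skin (0.00289) and the immediate early list between the allergens (0.0149) were called. The cause was not tested.

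No called named gene changed sign under any alternative. In 3783 recomputations of 158 named genes per comparison, the call was the same in 3341, 3363 and 3600, lost in 373, 379 and 83, and gained in 69, 41 and 100. In 545 recomputations of 26 lists it was the same in 472, 508 and 483, lost in 55, 24 and 30, and gained in 15, 11 and 32. The alternative that prefers plain probe sets was not run.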

Other observations

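The gene families below were chosen after their values were seen, by name alone, and the test of epidermal T cells was chosen before its result was seen; directions given for families were the same after quantile renormalisation and median centring.

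Interferon-induced GTPases followed the interferon lists. All 7 guanylate-binding protein genes and all 4 immunity-related GTPase genes, which act against intracellular microbes, rose in oxazolone skin, with medians of 3.61 and 5.25, and none was called by limma in urushiol skin, with medians of -0.433 and -0.685. Leaving out control array 3, 6 of the 7 and all 4 rose in oxazolone skin. Igtp, Iigp1 and Irgm1 stood at 5.62 ± 0.71, 5.98 ± 0.68 and 4.88 ± 0.56, and the direct difference passed for Gbp2, and for these 3 genes not in the 9-array fit but after median centring and without oxazolone array 2 or 3 (adjusted p from 0.0107 to 0.0268), among other alternatives.

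Several other families rose with both allergens. All 9 Sprr2 genes and all 6 late cornified envelope 3 genes, a group known from wounded epidermis, rose with each allergen, with medians of 5.82 and 6.51 in oxazolone and 7.88 and 7.86 in urushiol skin. Of the 6, 5 rose with oxazolone without control array 3, and the oxazolone call of Lce3a was lost without 4 arrays taken singly, at adjusted p up to 0.0651 (control array 2). Of 13 late cornified envelope 1 genes, 3 rose and 1 fell with oxazolone, and 4 rose and 1 fell with urushiol. Of 12 stefin genes 10 rose with each allergen, and of 10 kallikrein-related peptidases of the epidermis 7 rose with oxazolone and 9 with urushiol. Of 4 gasdermin C genes 2 rose with oxazolone and 4 with urushiol, and of 6 Tmprss11 proteases 3 and 4. All Sprr2, late cornified envelope 3, kallikrein and gasdermin C genes lay higher in urushiol than in oxazolone skin, by medians of 1.39, 1.57, 1.11 and 1.04, and limma called none of these differences (2, 3, 7 and 2 had an unadjusted p under 0.05). The gap junction genes Gjb2 and Gjb6 rose by 5.67 ± 0.96 and 4.69 ± 0.52 with oxazolone and by 5.98 ± 0.96 and 5.24 ± 0.52 with urushiol, and Gjb5 fell by 1.44 ± 0.15 and 1.82 ± 0.15.

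Skint genes fell with both allergens. Of 11 Skint genes, keratinocyte genes of which 1, Skint1, is known to select epidermal T cells in the thymus, 10 fell with oxazolone and 9 with urushiol, with medians of -2.66 and -2.78, and 8 fell with urushiol without control array 3. Of 42 collagen genes, 7 fell with oxazolone and 6 with urushiol, with medians of -0.02 and -0.05, and 1 rose with each, Col12a1 by 4.21 ± 0.78 and 3.50 ± 0.78, calls lost without 3 and 5 arrays taken singly, at adjusted p up to 0.0572 (control array 1) and 0.0911 (control array 2). Leaving out control array 3 gave 3 collagen genes that rose with oxazolone and 2 with urushiol, and after quantile renormalisation 11 fell with oxazolone. Of 7 Mas-related receptor genes of group b, 2 fell with each allergen, the mast cell genes Mrgprb2 and Mrgprb3, the latter by 5.94 ± 0.19 with oxazolone.

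Fewer dendritic epidermal T cells, resident lymphocytes of mouse epidermis, may lie behind the fall of Cd3e and Cd3g. Of 8 markers above the median of all clusters in control skin, 50% were called lower in urushiol skin, namely Cd7, Cd96 and the receptor segments Trgv5 (-3.03 ± 0.26) and Trdv4 (-0.68 ± 0.14), between the 60% this explanation needed and the 30% that would have argued against it. The calls of Trdv4 with urushiol and of Klrd1 with oxazolone were each lost without 4 arrays taken singly, at adjusted p up to 0.0689 (urushiol array 3) and 0.0771 (oxazolone array 1). Jaml, another of these markers, rose by 0.73 ± 0.11, and in oxazolone skin 3 of the 8 were called lower (Cd7, Trgv5 and Trdv4) and 2 higher (Jaml and Klrd1). Cd96 missed the threshold there at -0.69 ± 0.19 (adjusted p = 0.05) and passed it without oxazolone array 3 (0.041) or urushiol array 2 (0.0453), so the test leaves the explanation open, and other changes in T cells cannot be told apart from it with whole skin.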
